A study of Arabidopsis thaliana with 26 samples.

How the data were processed

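The series measured transcript levels on 26 single-channel oligonucleotide arrays of Arabidopsis T87 cultured cells treated with ABA, SA, methyl jasmonate, ABA with SA, ABA with methyl jasmonate, or ethanol, for 3 h or 24 h. Values were used as deposited: per the submitters' processing notes the authors made them by RMA, with 1 value per probe set and array, and the deposited values are log2 signals, a scale read from their range of 1.77 to 13.91. The RMA version is not given in the sources used here. All 22746 probe sets were used, with 0 missing values and 0 control probe sets in the table. Raw intensity files were not used here.

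Probe sets were matched to genes through a table of probe sets and gene identifiers, and genes were named from a reference annotation table (names only, no positions). Of the probe sets, 13436 matched 1 gene of that table and 77 matched 1 gene outside it, 503 matched several genes and 8730 had no gene. Unmatched probe sets were tested and counted but not named. In all 13286 genes had 1 matched probe set or more, and 144 had more than 1, in which case each probe set was tested by itself. Several widely used marker genes of the hormones are among the unmatched probe sets, so their absence from the text says nothing about their levels.

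Arrays were grouped by the source name in the labels, which for the 4 arrays with combined hormones at 3 h contradicts the title. Results that use these arrays were also computed with the groups of the titles. The 12 groups held 2 arrays each, except ABA alone with 3 at each time. One linear model of the 12 group means was fitted to all 26 arrays with limma 3.58.1 (R 4.3.3, statmod 1.5.0), with moderated t tests and residual spread pooled over the groups. P-values were adjusted by Benjamini and Hochberg over all probe sets of a comparison, and calls were made at adjusted p under 0.05. Counts at least 2-fold used the same calls. Each hormone was compared with the ethanol control of its time, each combination with the control and each single hormone, and the interaction was the change with both hormones minus the sum of the changes with each. Controls at 24 h and 3 h, and the hormone responses at both times, were compared in the same fit. Errors beside changes are standard errors of that fit, and errors beside levels are SDs between arrays.

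Named genes followed a rule written before the data were examined. For a single hormone they come from the 10 highest and 10 lowest matched genes among those called with every treated array beyond every control array. Only part of the genes under the rule are named in the Results. Larger changes can go unnamed there, such as AT2G04460 (-7.32) and AT1G62480 (-6.41) with ABA at 3 h. For combinations and interactions the named genes come from the 5 highest and 5 lowest, and measured members of the gene lists may also be named. Genes followed from one comparison into another, values of genes without a call, and levels on single arrays were chosen after their values were seen.

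Gene lists were tested with camera in limma with the preset correlation of 0.01 between genes, and again with the correlation estimated from the data. The 28 lists fixed at the start hold 382 members, of which 47 were measured under a name, and 6 lists had 3 or more measured. A further 25 lists with 614 members were drawn up from gene names and general knowledge once the annotation was read, before any test. Lists can share members. Of the 5 measured ABA response genes 4 are also late embryogenesis abundant genes, and all 4 measured photosynthesis genes are also nuclear photosynthesis genes. Results of such lists are therefore not independent. For fixed lists the genes were also adjusted over the list alone.

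Overlaps of calls between hormones share the controls. They were set beside the number for independent lists and beside 20 simulated draws in which no group changed. The procedure was tested on simulated data for SA at 3 h with 200 changed probe sets. It recovered 32% of changes of 1 log2 unit and 87% of those of 2 log2 units, with 100% of the signs right and 8 false calls. A list shifted in the same draw was found (camera adjusted p = 7.46e-36) and 0 of the other lists were called. The simulated probe sets varied independently of each other and alike in all groups. The draw therefore cannot show how often lists of correlated genes are called falsely.

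Alternatives were a fit of the groups compared alone, a trended robust variance prior, a replicate block, omission of the dimmest probe sets, quantile scaling, array weights, grouping by title, and leaving out each array in turn. In the last, a lone array left in a group was assumed to vary like the other groups. Leaving out replicate 1 of JA and of ABA+JA at 24 h together, averaging replicates 2 and 3 of ABA at 3 h, and a replicate block within each time were chosen after seeing the data. The place of each array on the difference between SA at 24 h and SA at 3 h was computed over 3242 probe sets that differed between those groups. With few arrays per group, most simulated changes of 1 log2 unit were missed.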

Results

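Transcript levels were measured on 26 arrays of Arabidopsis thaliana T87 cells, a suspension line kept in shaken flasks. The cells had received abscisic acid (ABA, 25 µM), salicylic acid (SA, 300 µM), methyl jasmonate (100 µM, called JA in the labels and here), ABA with SA, ABA with JA, or 0.6% ethanol as control, for 3 h or 24 h. ABA is a hormone of drought and osmotic stress, SA of defence against biotrophic pathogens, and JA of wounding and defence against herbivores. The series asked how the hormones act on one another, from responses to single hormones and to pairs. Each of the 12 groups held 2 arrays, except ABA alone with 3 arrays at each time. The 22746 probe sets had log2 values between 1.77 and 13.91, and the number of arrays limits the precision of every comparison. Nothing in the labels says that replicates came from separate cultures, so p-values measure only the spread between these arrays, which may be technical.

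Replicate arrays correlated at r = 0.9458 to 0.9885 across probe sets, which are not independent replicates. Replicates 2 and 3 of ABA at 3 h were closer, at r = 0.9975. The SD of their difference was 0.158 log2 units, against 0.343 to 0.735 for other replicate pairs. They differed by less than the noise seen between other replicates and were counted as 1 sample in each mean ± SD (n = 2 there), while the fit used all 26 arrays.

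The labels of the 4 arrays with combined hormones at 3 h contradict each other. Their titles name ABA+JA where the source name, treatment entry and protocol name ABA+SA, and the reverse. Groups follow the source name, and these arrays are called arrays labelled ABA+SA or labelled ABA+JA at 3 h. JRG21 (AT3G55970), which encodes an oxygenase that hydroxylates jasmonic acid, read 11.57 ± 0.58 (SD, n = 2) with JA alone at 3 h and 2.99 ± 0.14 (n = 2) in the control. It read 10.87 ± 0.63 (n = 2) in the arrays labelled ABA+SA and 3.00 ± 0.09 (n = 2) in those labelled ABA+JA. UGT76B1 (AT3G11340), whose product glucosylates SA, read 10.83 ± 0.74 (n = 2) with SA alone at 3 h, 8.47 ± 0.61 (n = 2) in the arrays labelled ABA+SA and 11.74 ± 0.31 (n = 2) in those labelled ABA+JA. Across probe sets, the difference ABA+SA minus ABA+JA correlated with SA minus JA at r = -0.357 at 3 h and r = 0.727 at 24 h, where title and source name match. Of 146 probe sets that differed between SA and JA alone at 3 h, 128 had the opposite sign between the combined arrays, against 76 of 1305 at 24 h. Over 16 sets of single arrays the correlation ranged from -0.416 to 0.115 at 3 h and from 0.26 to 0.703 at 24 h. At 24 h the JA and ABA+JA arrays also lay nearer to 3 h arrays than the SA and ABA+SA arrays did, as given below. The 24 h values may therefore not measure the hormones alone.

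**Figure D1:**
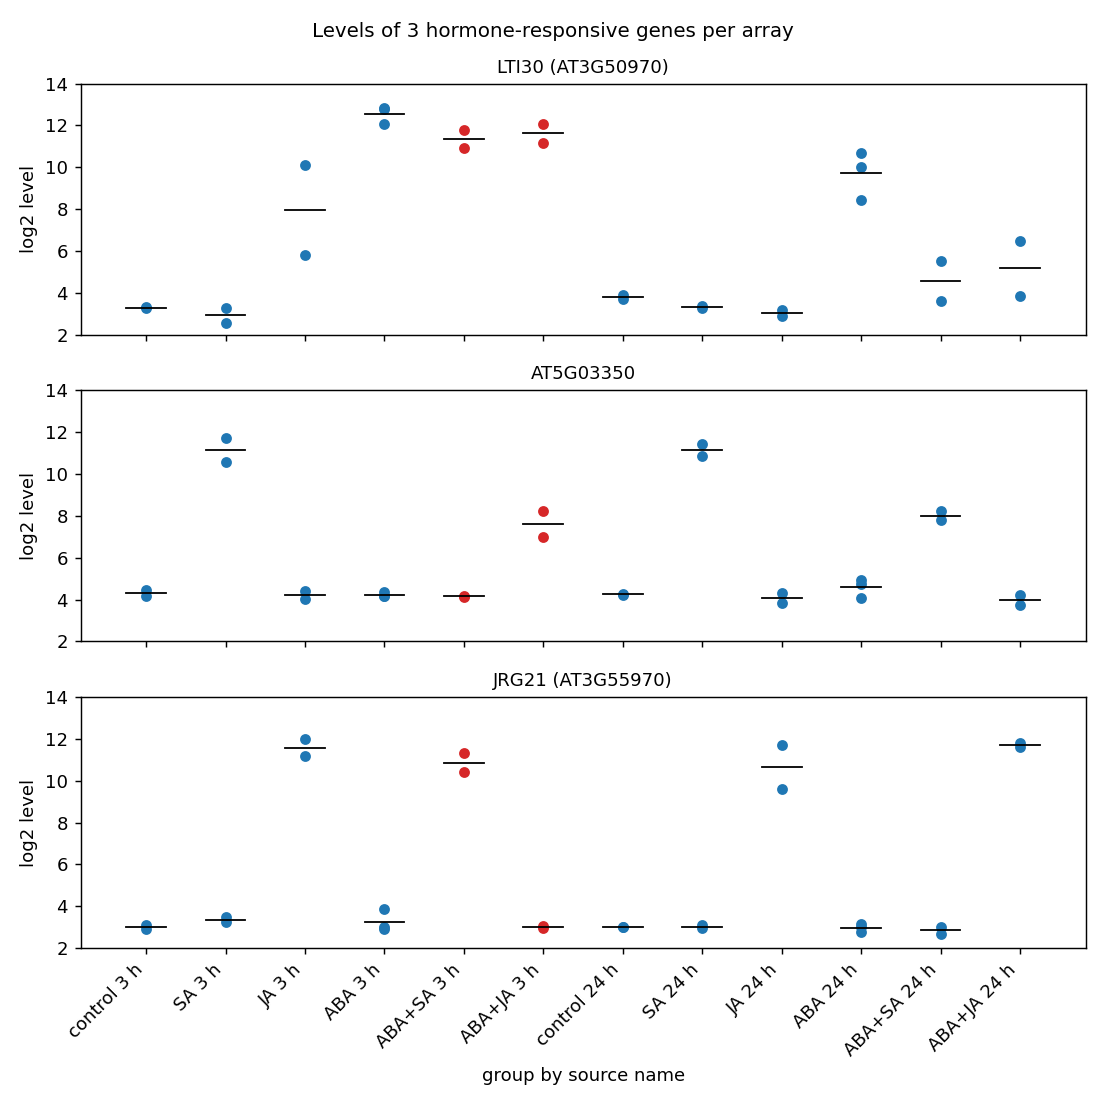
Log2 level (vertical axis) of LTI30, AT5G03350 and JRG21 on each array (points) by group (horizontal axis, group by source name), with the group mean as a line over all arrays and the 3 h arrays of contradictory labels in red. JRG21 read 10.43 and 11.31 on the arrays labelled ABA+SA at 3 h, and 3.06 and 2.94 on those labelled ABA+JA.

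Control cells changed between 3 h and 24 h, with 1653 probe sets higher and 885 lower at 24 h. The total of 2538 was 799 to 1162 without any 1 control array. Of 118 genes of cytosolic ribosomal proteins, 82 rose and none fell (median log2 change 0.98, camera adjusted p = 6.07e-42), with adjusted p = 0.167 with an estimated correlation. Among 16 genes of mitosis, 8 rose (median 2.01, camera adjusted p = 1.56e-11), with adjusted p = 0.349 with an estimated correlation. Of 10 autophagy genes 4 fell (median -0.93, camera adjusted p = 3.89e-05), with adjusted p = 0.349 with an estimated correlation. Over the 3242 probe sets that differed between SA at 24 h and SA at 3 h, each array was placed on an axis where SA at 3 h is 0 and SA at 24 h is 1. The control arrays lay at 0.0996 and 0.128 at 3 h and at 0.893 and 0.971 at 24 h. Replicate 1 of JA at 24 h lay at 0.105 and replicate 2 at 0.624, and replicate 1 of ABA+JA at 24 h at 0.13 and replicate 2 at 0.307. The arrays of ABA alone lay between 0.402 and 0.549 at both times, and the combined arrays at 3 h between -0.219 and -0.157.

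**Figure D2:**
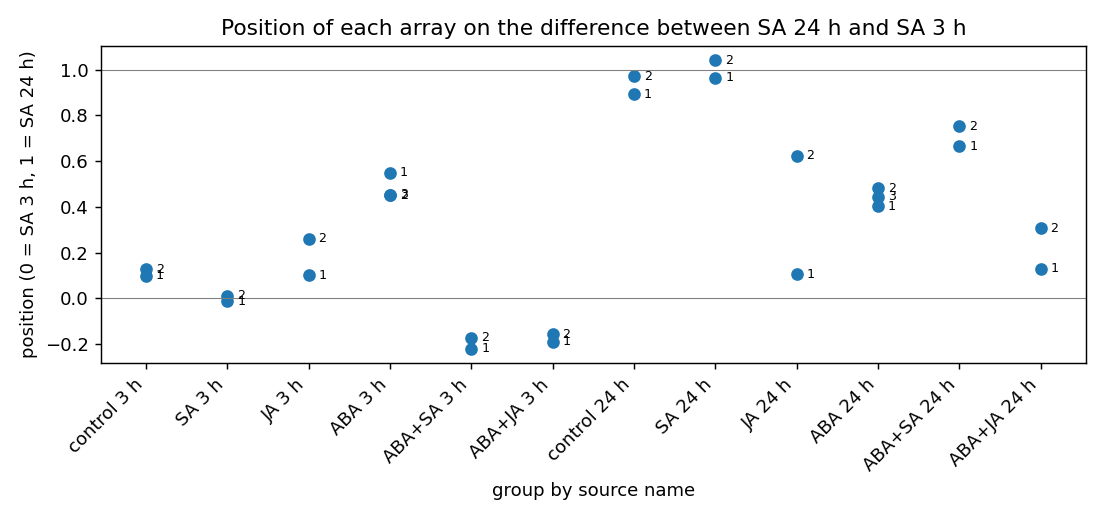
Position of each array (vertical axis, no unit) on the difference between SA at 24 h (1) and SA at 3 h (0), over 3242 probe sets, by group (horizontal axis, group by source name); each point is 1 array with its replicate number. Replicate 1 of JA and of ABA+JA at 24 h lay at 0.105 and 0.13, near the 3 h controls.

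ABA for 3 h raised stress-protection genes. LTI30 (AT3G50970), a dehydrin, rose by 9.27 ± 0.95 (SE) log2 units, from 3.29 ± 0.06 (SD, n = 2) in the control to 12.45 ± 0.50 (n = 2). LEA4-5 (AT5G06760), a late embryogenesis abundant protein of water-deficit tolerance, rose by 7.03 ± 0.36 (limma adjusted p = 3.35e-09), and COR15A (AT2G42540), a chloroplast protein of freezing tolerance, by 5.48 ± 0.62 (adjusted p = 1.73e-05). AT3G02480, of the late embryogenesis abundant family, rose by 8.38 ± 0.86 (adjusted p = 6e-06). AT1G49450, AT2G37870, AT5G22460, AT3G22620, AT2G16630 and AT2G47780 rose by 5.39 to 7.12. The peroxidase gene AT5G17820 fell by 4.57 ± 0.41 (adjusted p = 1.81e-06), and AT1G68670 and AT5G19120 fell too (-5.65 ± 0.36 and -7.73 ± 1.03). GAT1_2.1 (AT1G15040), a glutamine amidotransferase-like gene, fell by 6.17 ± 1.37 (adjusted p = 0.00427), while its other probe set read -0.98 (adjusted p = 0.315). It read 4.333 to 4.892 with ABA alone at 3 h, but 9.672 to 10.14 on the 4 combined arrays at 3 h, which also had ABA. The controls read 10.49 and 11.11 at 3 h, and 3.997 and 4.342 at 24 h. The fall of GAT1_2.1 may therefore not measure ABA alone.

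Of the 5 measured genes fixed as ABA response genes, LTI30, LEA4-5 and COR15A rose after 3 h, 4 rose when adjusted over the list alone, and HIS1-3 (AT2G18050), a drought-inducible linker histone, read -0.18 ± 0.87 (adjusted p = 0.918). The list stood above other probe sets (median 5.48, camera adjusted p = 1.83e-05), with adjusted p = 0.0648 with an estimated correlation. Of 23 late embryogenesis abundant genes, 4 of them also ABA response genes, 16 rose and 1, AT1G54410, fell (median 2.21, camera adjusted p = 3.14e-11; adjusted p = 0.0648 with an estimated correlation). Of 32 nuclear genes of photosynthesis and chlorophyll synthesis 24 fell (median -1.34, camera adjusted p = 6.39e-14; adjusted p = 0.0778 with an estimated correlation). Among them CHLM, a chlorophyll synthesis methyltransferase, fell by 2.13 ± 0.26 and PSAN, a photosystem I subunit, fell by 2.63 ± 0.31. Of the 4 measured genes of the fixed photosynthesis list, all also among these 32, 3 fell, also when adjusted over the list alone (median -1.17, camera adjusted p = 0.0196; adjusted p = 0.454 with an estimated correlation). Cytosolic ribosomal protein genes rose in 55 of 118 cases (median 0.61, camera adjusted p = 3.7e-17; adjusted p = 0.283 with an estimated correlation). Of 16 mitosis genes 6 rose, among them AUR2, an aurora kinase, by 2.98 ± 0.43 (list median 1.13, camera adjusted p = 9.3e-06; adjusted p = 0.469 with an estimated correlation). On the time axis these arrays lay at 0.451 to 0.549, against 0.0996 and 0.128 for their controls.

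ABA at 3 h called 1778 probe sets higher and 2337 lower, 2584 of them at least 2-fold. The total of 4115 was 1966 without control replicate 1 and 2170 without control replicate 2. Without control replicate 1 the call of GAT1_2.1 was lost (adjusted p = 0.0511).

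ABA for 24 h again raised AT3G02480, LEA4-5 and LTI30. AT3G02480 rose by 8.91 ± 0.86 (SE) to 12.41 ± 0.54 (SD, n = 3), LEA4-5 by 6.39 ± 0.36 (limma adjusted p = 9.7e-09) and LTI30 by 5.91 ± 0.95 (adjusted p = 0.000337). OSM34 (AT4G11650), an osmotin-like defence protein, rose by 7.74 ± 0.71 (adjusted p = 1.55e-06), from 4.05 ± 0.34 (n = 2) to 11.79 ± 0.58 (n = 3). OSM34 had not risen with ABA at 3 h (-0.64 ± 0.71, adjusted p = 0.601), and in the controls it fell by 6.48 ± 0.78 from 3 h to 24 h. ZW9 (AT1G58270), AT5G22460, AT2G37870, AT2G16630, AT5G07330 and AT4G23670 rose by 6.03 to 7.88. AT3G15630 fell by 4.75 ± 0.60. 3xHMG-box2 (AT4G23800), a protein that binds mitotic chromosomes, fell by 4.17 ± 0.83 (adjusted p = 0.00197). PR-1-LIKE (AT2G19990) fell too (adjusted p = 0.00911), a call lost without control replicate 2 (adjusted p = 0.101).

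All 5 measured ABA response genes rose at 24 h, also when adjusted over the list alone, with HIS1-3 at 5.75 ± 0.87 and COR47, a dehydrin, at 3.93 ± 0.92 (list median 5.75, camera adjusted p = 1.92e-07; adjusted p = 0.0268 with an estimated correlation). Of 23 late embryogenesis abundant genes 15 rose and AT2G46140 fell (median 3.41, camera adjusted p = 9.03e-11; adjusted p = 0.0433 with an estimated correlation). Of 14 ABA-associated genes 9 rose (median 1.67, camera adjusted p = 2.46e-10; adjusted p = 0.0268 with an estimated correlation). Mitosis genes fell in 15 of 16 cases (median -2.87, camera adjusted p = 1.2e-11; adjusted p = 0.2 with an estimated correlation), among them AUR1 (-3.32 ± 0.76) and KINESIN-12B (-2.61 ± 0.25). Of 50 UDP-glycosyltransferase genes 13 rose and 2 fell (median 0.27, camera adjusted p = 0.000395; adjusted p = 0.211 with an estimated correlation). Ribosomal protein genes fell in 15 of 118 cases and rose in 1 (median -0.28, camera adjusted p = 0.00157; adjusted p = 0.67 with an estimated correlation). These arrays lay at 0.402 to 0.481 on the time axis, against 0.893 and 0.971 for their controls. In all, 1601 probe sets were higher and 2566 lower with ABA at 24 h, and the total of 4167 was 2478 without control replicate 1 and 2041 without control replicate 2.

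The ABA response differed between the times. Mitosis genes changed more downward at 24 h than at 3 h in 15 of 16 cases (median difference -4.27, camera adjusted p = 1.61e-19; adjusted p = 0.197 with an estimated correlation). Ribosomal protein genes did so in 43 of 118 cases (median -0.92, camera adjusted p = 5.85e-25; adjusted p = 0.337 with an estimated correlation). Of 32 nuclear photosynthesis genes 10 changed more upward and 1 more downward (median 0.74, camera adjusted p = 1.8e-07; adjusted p = 0.388 with an estimated correlation). The 5 ABA response genes did not shift as a list (camera adjusted p = 0.995), and 1 of them changed more upward, also when adjusted over the list alone. In limma, 906 probe sets changed more upward and 1264 more downward at 24 h. The total of 2170 was 1152 and 1173 without control replicates 1 and 2 at 3 h, and 1367 and 1210 without those at 24 h. The arrays of ABA alone held nearly the same place on the time axis at both times while their controls did not, and the same lists differed between the controls.

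**Figure D3:**
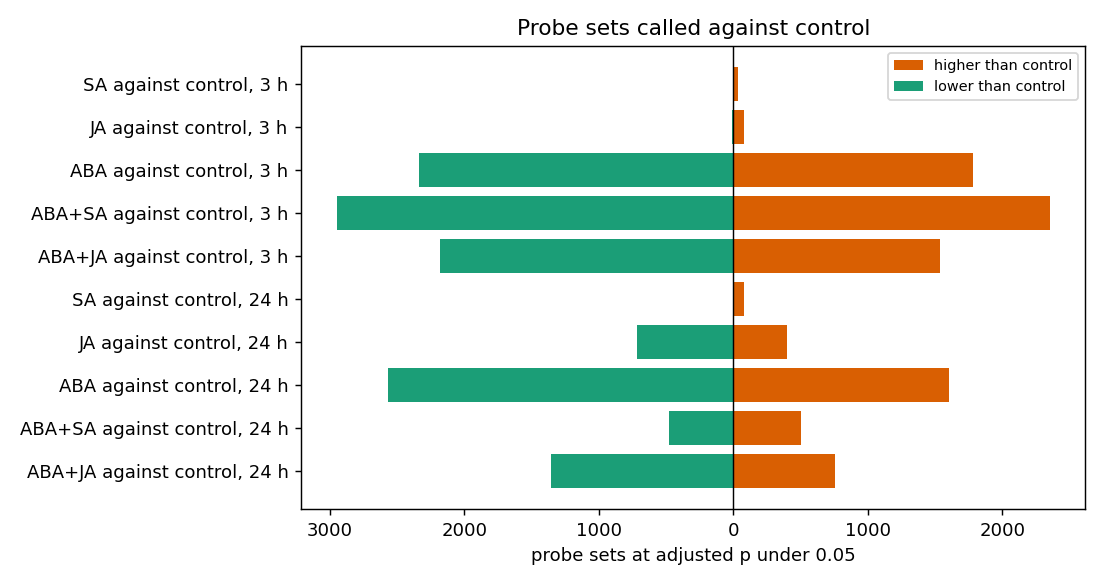
Number of probe sets (horizontal axis) higher (right) and lower (left) than the control of the same time at adjusted p under 0.05, for each treatment by source name (vertical axis). ABA alone gave 1778 higher and 2337 lower at 3 h, and SA alone 31 higher and 1 lower.

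SA alone gave few calls, and most of them were higher. AT5G03350, a legume lectin-like gene, rose by 6.87 ± 0.39 (SE) at 3 h (limma adjusted p = 1.62e-08) and 6.90 ± 0.39 at 24 h (adjusted p = 5.01e-09). It read 11.16 ± 0.82 (SD, n = 2) with SA and 4.29 ± 0.20 (n = 2) in the control at 3 h. AT1G19960 rose by 5.79 ± 0.29 at 3 h and 6.56 ± 0.29 at 24 h, and UGT76B1 by 5.22 ± 0.45 and 6.02 ± 0.45. AT5G41280 rose by 3.41 ± 0.34 at 3 h and 5.74 ± 0.34 at 24 h. AT1G15640 rose by 3.02 ± 0.25 at 3 h and 5.44 ± 0.25 at 24 h, and this difference with time passed the test (2.43 ± 0.36, adjusted p = 0.00832). AT5G22555 rose by 5.29 ± 0.18 at 24 h (adjusted p = 3.7e-12), and its change with time was 4.91 ± 0.25 (adjusted p = 4.75e-09). cwINV6 (AT5G11920), a fructan exohydrolase, rose by 5.35 ± 0.65 at 24 h (adjusted p = 0.000121).

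Of 15 SA-associated genes, AT5G03350 and UGT76B1 rose at 3 h (camera adjusted p = 2.67e-06; adjusted p = 0.0582 with an estimated correlation). At 24 h GRX480, a glutaredoxin that binds TGA factors, rose too, by 2.35 ± 0.46 (adjusted p = 0.0256), and the list again stood above other probe sets (camera adjusted p = 7.77e-14; adjusted p = 0.00146 with an estimated correlation). WRKY53, the other measured gene of the fixed SA response list, read -0.35 ± 1.19 at 24 h (adjusted p = 1). SA called 31 probe sets higher and 1 lower at 3 h, and 82 higher and 3 lower at 24 h. At an unadjusted p under 0.05 there were 776 and 567, less than the 0.05 share of 22746 probe sets that unchanged groups would give. The test may therefore have been too strict here, and the low counts do not show that few genes changed. The lower probe set at 3 h has no gene name in the table used. Fitted to the groups compared alone, the 24 h total of 85 was 28.

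After JA for 3 h, JRG21 rose by 8.58 ± 0.48 (SE; limma adjusted p = 9.06e-09), AT2G38240 by 6.89 ± 0.36 and AT5G05600 by 5.82 ± 0.43, all of the oxygenase family that hydroxylates jasmonic acid. AT1G06620, another oxygenase-like gene, rose by 4.32 ± 0.33. JAL33 (AT3G16450), a jacalin-related lectin, rose from 5.12 ± 0.21 (SD, n = 2) to 10.12 ± 0.44 (n = 2; adjusted p = 0.0001). PYK10 (AT3G09260), the beta-glucosidase of endoplasmic reticulum bodies, rose by 4.35 ± 0.78 (adjusted p = 0.0134), from 3.46 ± 0.65 (SD, n = 2) to 7.81 ± 0.01 (n = 2). The PYK10 call was lost without any 1 of the 4 arrays, with adjusted p = 0.256 and 0.0694 without control replicates 1 and 2, and 0.129 and 0.132 without JA replicates 1 and 2. TET2 (AT2G19580), a tetraspanin, fell by 1.07 ± 0.21 (adjusted p = 0.0226), a call lost without control replicate 1 or 2 (adjusted p = 0.0885 and 0.402) and without JA replicate 1 or 2 (adjusted p = 0.107 and 0.295), and when fitted to the groups compared alone (adjusted p = 0.267).

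Of 13 JA-associated genes JRG21, AT2G38240 and AT5G05600 rose at 3 h (camera adjusted p = 2.05e-09; adjusted p = 0.00344 with an estimated correlation). The 3 measured genes of the fixed JA response list, all defensin or thionin genes, had no call in limma, nor when adjusted over the list alone. LTI30 read 5.81 and 10.13 on the JA arrays at 3 h, a difference from the control of 4.67 that did not pass the test (adjusted p = 0.0732). JA at 3 h called 76 probe sets higher and 9 lower, with 1252 at an unadjusted p under 0.05. The total of 85 was 44 and 41 without control replicates 1 and 2, 49 and 53 without JA replicates 1 and 2, and 37 when fitted to the groups compared alone.

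After JA for 24 h, PYK10 rose by 7.74 ± 0.78 (SE; limma adjusted p = 1.66e-05), JAL33 by 7.62 ± 0.57 and NAI2 (AT3G15950), needed to form endoplasmic reticulum bodies, by 4.93 ± 0.78. JRG21 rose by 7.64 ± 0.48 and AT5G05600 by 5.52 ± 0.43. AT2G38240 rose by 2.97 ± 0.36, less than at 3 h (change with time -3.92 ± 0.51, adjusted p = 0.00591). OSM34 rose by 5.12 ± 0.78, or by 3.57 (adjusted p = 0.0208) without replicate 1 of JA. It read 10.7 and 7.621 on replicates 1 and 2, and 9.985 and 11.07 on the 3 h control arrays, near which replicate 1 lay on the time axis. NRT2.5 (AT1G12940), a nitrate transporter, fell by 3.39 ± 0.57 (adjusted p = 0.00252) and AT1G73600 fell by 3.22 ± 0.47. TOPII (AT3G23890), DNA topoisomerase II, fell by 3.27 ± 0.70 and the plastid ribosomal gene rps3 fell by 4.92 ± 0.96, but both calls were lost without replicate 1 of JA (-2.33 and -3.98, adjusted p = 0.178 and 0.11). They were also lost without a control array, TOPII at adjusted p = 0.0685 and 0.0756 without replicates 1 and 2, and rps3 at 0.0703 without replicate 2.

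Cytosolic ribosomal protein genes fell in 38 of 118 cases with JA at 24 h (median -0.69, camera adjusted p = 1.24e-30; adjusted p = 0.217 with an estimated correlation). Mitosis genes fell in 6 of 16 cases (median -2.02, camera adjusted p = 1.29e-11; adjusted p = 0.229 with an estimated correlation). Of 20 plastid-encoded genes of gene expression 5 fell (median -0.98, camera adjusted p = 6.06e-05; adjusted p = 0.393 with an estimated correlation). JRG21, AT5G05600 and AT2G38240 were the JA-associated genes that rose (list camera adjusted p = 0.00174; adjusted p = 0.217 with an estimated correlation). On the axis between SA at 3 h and SA at 24 h, JA replicate 1 lay at 0.105 and replicate 2 at 0.624, against 0.893 and 0.971 for the controls, and the ribosomal and mitosis genes also differ along that axis. JA at 24 h called 395 probe sets higher and 715 lower, or 451 and 512 after quantile scaling. The total of 1110 was 271 without JA replicate 1 and 2209 without JA replicate 2, 284 and 538 without control replicates 1 and 2, and 390 without replicate 1 of both JA and ABA+JA. Fitted to the groups compared alone, limma called 0, PYK10 and JRG21 included (adjusted p = 0.251 and 0.223).

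**Figure D4:**
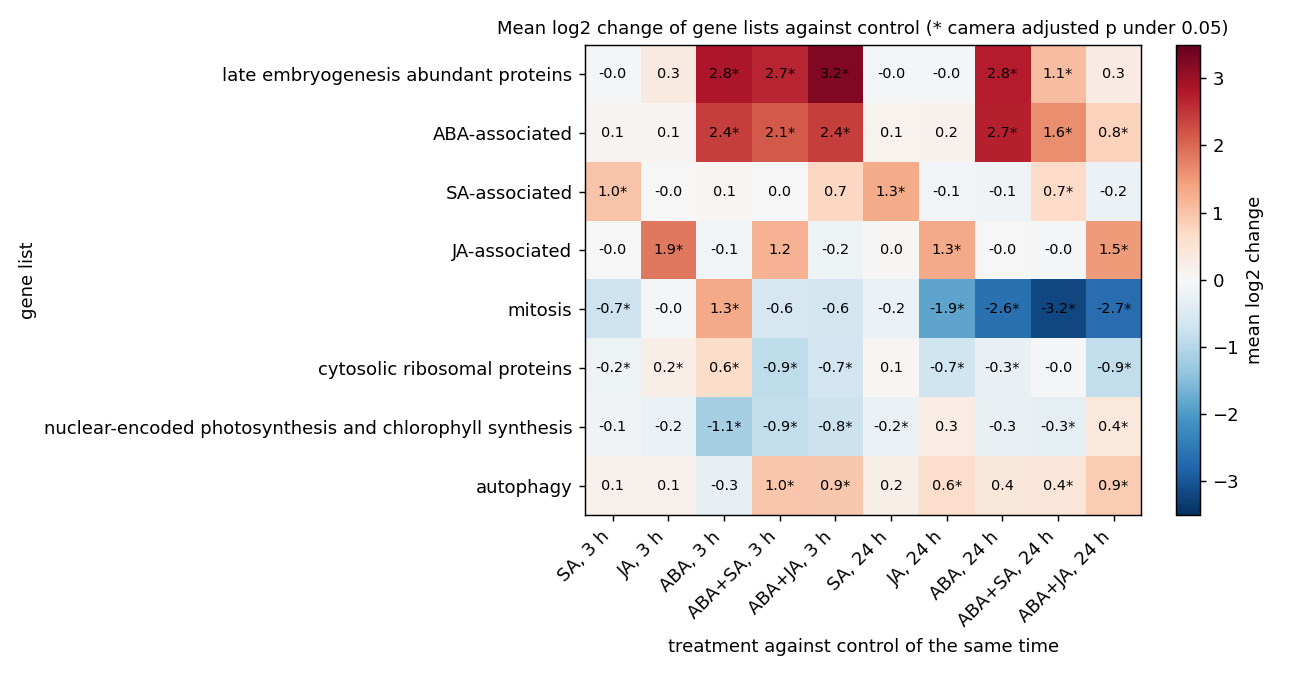
Mean log2 change against the control of the same time (colour and number) of 8 gene lists (vertical axis) under each treatment by source name (horizontal axis); an asterisk marks a camera adjusted p under 0.05 with the preset correlation. Late embryogenesis abundant genes had a mean of 2.84 with ABA at 3 h and 2.75 at 24 h.

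Calls of ABA and of a second hormone against the same controls overlapped, not all in the same direction. Opposite directions were seen in 11 probe sets for ABA and JA and 2 for ABA and SA at 3 h. For ABA and SA at 24 h there were 5. At 24 h ABA and JA shared 576 probe sets in the same direction, 166 higher and 410 lower, with 8 opposite, where independent lists would share 108. Their changes correlated at r = 0.483, against 0.547 simulated for unchanged groups with shared controls, and their covariance was 0.281 against 0.065 simulated. The 576 were 122 to 1060 without any 1 array, lowest and highest without replicates 1 and 2 of JA, 188 without replicate 1 of both JA and ABA+JA, and 91 when fitted to the groups compared alone. On the time axis ABA alone at 24 h lay at 0.402 to 0.481 and JA at 0.105 and 0.624, both below the controls at 0.893 and 0.971. At 3 h ABA and JA shared 23 in the same direction (6.87 for independent lists), with r = 0.309 against 0.546 and covariance 0.111 against 0.065, and the 23 were 9 to 29 without any 1 array. ABA and SA shared 6 at 3 h (2.53 for independent lists), with r = 0.142 against 0.549 and covariance 0.0398 against 0.0652, and the 6 were 3 to 7 without any 1 array and 3 when fitted to the groups compared alone. At 24 h ABA and SA shared 17 (6.11), with r = 0.212 against 0.546 and covariance 0.0659 against 0.0649. The 17 were 6 to 39 without any 1 array, lowest and highest without control replicates 1 and 2, and 9 when fitted to the groups compared alone. Unchanged groups shared a mean of 0 to 0.05 calls in 20 simulated draws, a number near 0 where nothing changed, so that it gives no measure of an excess. The draws held no pairing of arrays with the same number, of which the data give a hint within a time (below). The simulated r and covariance are therefore only a rough guide. The controls were not split, since each part would hold 1 array, and part of an overlap above the number for independent lists may come from the shared controls.

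In the arrays labelled ABA+SA at 3 h, AT3G02480 rose against the control by 8.12 ± 0.94 (SE; limma adjusted p = 1.07e-05), LTI30 by 8.07 ± 1.04 and AT1G49450 by 7.39 ± 0.70. In those labelled ABA+JA the same genes rose by 8.84 ± 0.94, 8.33 ± 1.04 and 8.11 ± 0.70. JRG21 rose by 7.88 ± 0.48 in the arrays labelled ABA+SA, and read 0.01 ± 0.48 (adjusted p = 0.994) in those titled ABA+SA. AT5G64100, a peroxidase gene, fell by 4.69 ± 0.77 in the arrays labelled ABA+SA and 4.03 ± 0.77 in those labelled ABA+JA. Late embryogenesis abundant genes rose in 11 of 23 cases labelled ABA+SA (median 1.87, camera adjusted p = 4.59e-07; adjusted p = 0.217 with an estimated correlation) and 16 of 23 labelled ABA+JA (median 3.45, camera adjusted p = 8.24e-15; adjusted p = 0.0392 with an estimated correlation). Ribosomal protein genes fell in 81 of 118 cases labelled ABA+SA (median -0.90, camera adjusted p = 1.3e-23; adjusted p = 0.217 with an estimated correlation). They fell in 52 labelled ABA+JA (median -0.63, camera adjusted p = 3.43e-17; adjusted p = 0.264 with an estimated correlation). The autophagy gene ATG8H rose by 4.12 ± 0.45 and 3.93 ± 0.45 in the respective arrays. All 4 arrays lay below the 3 h controls on the time axis, along which the ribosomal genes also differ.

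The arrays labelled ABA+SA differed from the control in 2352 probe sets higher and 2948 lower, and those labelled ABA+JA in 1532 higher and 2181 lower. The sets shared 3197 probe sets, 3194 in the same direction, and were tested against the same controls. The total of 5300 for the arrays labelled ABA+SA was 3204 and 3440 without control replicates 1 and 2, and 3324 without replicate 1 of the combined arrays. The total of 3713 for those labelled ABA+JA was 2129 and 2248 without control replicates 1 and 2, and 2280 and 2378 without replicates 1 and 2 of the combined arrays. Between the arrays labelled ABA+SA and those labelled ABA+JA 66 probe sets were higher and 36 lower. Against SA alone, 1920 were higher and 2471 lower in the arrays labelled ABA+SA, and by title 1299 and 1733. That total of 4391 was 2737 and 2759 without SA replicates 1 and 2, and 2565 without replicate 1 of the combined arrays. Against JA alone, 1434 were higher and 2198 lower in the arrays labelled ABA+JA, and by title 2101 and 2710. That total of 3632 was 1972 without JA replicate 2, and 1995 and 2361 without replicates 1 and 2 of the combined arrays.

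Against ABA alone at 3 h, ribosomal protein genes fell in 109 of 118 cases labelled ABA+SA (median -1.53, camera adjusted p = 3.53e-55; adjusted p = 0.0632 with an estimated correlation). They fell in 105 cases labelled ABA+JA (median -1.27, camera adjusted p = 1.47e-49; adjusted p = 0.0939 with an estimated correlation). Mitosis genes fell in 12 and 11 of 16 cases (camera adjusted p = 3.37e-06 and 2.29e-07; adjusted p = 0.601 and 0.747 with an estimated correlation), and autophagy genes rose in 8 of 10 in each (camera adjusted p = 4.84e-05 and 4e-06; adjusted p = 0.496 and 0.354 with an estimated correlation). The arrays of ABA alone lay at 0.451 to 0.549 on the time axis and the combined arrays at -0.219 to -0.157. In all, 2829 probe sets were higher and 2803 lower in the arrays labelled ABA+SA, and 2186 higher and 2495 lower in those labelled ABA+JA. The total of 5632 was 3619 without replicate 1 labelled ABA+SA, and that of 4681 was 2522 and 2482 without replicates 1 and 2 labelled ABA+JA.

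The interaction at 3 h, the change with both hormones minus the sum of the changes with each, depended on the labels for hormone-specific genes. For ABA with SA, JRG21 read 7.26 ± 0.65 (SE; limma adjusted p = 7.42e-06) by source name and -0.62 ± 0.65 (adjusted p = 0.677) by title. AT5G03350 was below the sum of both changes by either, at -6.94 ± 0.53 by source name and -3.49 ± 0.53 by title (adjusted p = 0.00241). For ABA with JA, JRG21 read -8.84 ± 0.65 by source name and -0.96 ± 0.65 (adjusted p = 0.404) by title, and AT2G38240 -7.11 ± 0.49 and -2.15 ± 0.49 (adjusted p = 0.00973). AtLEA4-1 (AT1G32560) was above the sum for ABA with SA, by 4.83 ± 0.75 and 4.68 ± 0.75, and AT5G62350 below it for ABA with JA, at -6.37 ± 0.94 and -5.94 ± 0.94. Ribosomal protein genes lay below the sum in 81 of 118 cases for SA (median -1.34, camera adjusted p = 8.67e-51; adjusted p = 0.0859 with an estimated correlation). They did so in 87 for JA (median -1.60, camera adjusted p = 9.56e-57; adjusted p = 0.0568 with an estimated correlation). The term subtracts the arrays of ABA alone, which lay apart from other 3 h arrays on the time axis.

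For ABA with SA at 3 h, 703 probe sets lay above the sum and 936 below it, and 369 and 515 by title. That total of 1639 was 951 and 766 without control replicates 1 and 2, 751 and 1025 without SA replicates 1 and 2, and 936 without replicate 1 labelled ABA+SA. For ABA with JA, 759 lay above and 1062 below, and 881 and 1275 by title. That total of 1821 was 972 and 876 without control replicates 1 and 2, 738 without JA replicate 2, and 958 and 1007 without replicates 1 and 2 labelled ABA+JA.

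ABA+SA for 24 h raised genes of both hormones. AT1G19960 rose by 7.48 ± 0.29 (SE; limma adjusted p = 2.35e-11) against the control, UGT76B1 by 5.42 ± 0.45 and AT5G03350 by 3.76 ± 0.39. AT2G37870 rose by 7.37 ± 1.13, AT3G02480 by 6.39 ± 0.94, OSM34 by 5.99 ± 0.78 and LEA4-5 by 3.41 ± 0.40. 3xHMG-box2 fell by 5.22 ± 0.91 (adjusted p = 0.00209). Mitosis genes fell in 14 of 16 cases (median -2.90, camera adjusted p = 9.84e-29; adjusted p = 0.0473 with an estimated correlation). The ABA+SA arrays lay at 0.665 and 0.753 on the time axis, along which mitosis genes also differ, against 0.893 and 0.971 for the controls. Late embryogenesis abundant genes rose in 6 of 23 cases and 1 fell (median 1.05, camera adjusted p = 0.000105; adjusted p = 0.334 with an estimated correlation). Of the 5 ABA response genes LEA4-5 rose, and 2 rose when adjusted over the list alone (median 2.27, camera adjusted p = 0.000244; adjusted p = 0.124 with an estimated correlation). In all, 504 probe sets were higher and 480 lower. The total of 984 was 550 and 544 without control replicates 1 and 2, and 547 and 495 without replicates 1 and 2 of ABA+SA.

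Against SA alone at 24 h, AT5G22555 fell by 4.87 ± 0.18 with ABA+SA (adjusted p = 1.56e-11), and cwINV6 and AT5G03350 fell too (-4.60 ± 0.65 and -3.14 ± 0.39), while UGT76B1 read -0.59 ± 0.45 (adjusted p = 0.902). Here 271 probe sets were higher and 345 lower, and the total of 616 was 285 and 170 without SA replicates 1 and 2, and 257 and 252 without replicates 1 and 2 of ABA+SA. Against ABA alone (0.402 to 0.481 on the time axis, ABA+SA at 0.665 and 0.753), late embryogenesis abundant genes fell in 10 of 23 cases (median -1.71, camera adjusted p = 2.32e-09; adjusted p = 0.0922 with an estimated correlation). In the same comparison ABA response genes fell in 3 of 5, or 4 when adjusted over the list alone (median -2.92, camera adjusted p = 1.71e-05; adjusted p = 0.0922 with an estimated correlation). Here 1035 probe sets were higher and 550 lower, and the total of 1585 was 934 and 395 without replicates 1 and 2 of ABA+SA, and 452 when fitted to the groups compared alone.

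In the interaction of ABA and SA at 24 h, some genes that ABA or SA raised lay below the sum. The term subtracts the arrays of ABA alone, which lay at 0.402 to 0.481 on the time axis, against 0.893 and 0.971 for the controls. The interaction with JA at 24 h subtracts the same arrays. AT2G16630, raised by ABA, read -6.58 ± 0.56 (adjusted p = 1.16e-05), and AT5G22555 and cwINV6, raised by SA, -4.94 ± 0.24 and -5.05 ± 0.88 (adjusted p = 2.03e-09 and 0.00817). AT5G03350 read -3.47 ± 0.53 (adjusted p = 0.00295) and LEA4-5 -3.21 ± 0.54 (adjusted p = 0.00589). UGT76B1 and AT1G19960, which SA also raised, had no call (-0.15 and 1.42, adjusted p = 0.959 and 0.126). AT5G26270 lay above the sum by 3.74 ± 0.41 (adjusted p = 0.000155). Of 23 late embryogenesis abundant genes 2 lay below the sum (median -1.64, camera adjusted p = 5.05e-08; adjusted p = 0.0754 with an estimated correlation). Of the 5 ABA response genes LEA4-5 did, and 3 did when adjusted over the list alone (median -3.21, camera adjusted p = 7.17e-05; adjusted p = 0.0754 with an estimated correlation). In all, 57 probe sets lay above the sum and 108 below it, or 37 and 103 after quantile scaling. The total of 165 was 83 and 92 without control replicates 1 and 2, 76 without SA replicate 1 and 83 without replicate 2 of ABA+SA.

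ABA+JA for 24 h raised genes that JA alone also raised. JRG21 rose by 8.71 ± 0.48 (SE; limma adjusted p = 2.14e-08) against the control, PYK10 by 8.36 ± 0.78, JAL33 by 8.05 ± 0.57 and OSM34 by 7.02 ± 0.78. Fitted to the groups compared alone, the PYK10 call was lost (adjusted p = 0.057). ABA alone at 24 h raised PYK10, JAL33 and OSM34 too, by 4.96 ± 0.71, 3.41 ± 0.52 and 7.74 ± 0.71. PYK10 read 10.75 ± 1.80 (SD, n = 2) with JA alone and 11.37 ± 2.15 (n = 2) with ABA+JA. Late embryogenesis abundant genes had no call against the control in limma, and AT3G02480 read 5.27 ± 3.32 (n = 2) with ABA+JA, against 12.41 ± 0.54 (n = 3) with ABA alone. Of the 5 ABA response genes 1 rose, or 3 when adjusted over the list alone (median 1.37, camera adjusted p = 0.00897; adjusted p = 0.216 with an estimated correlation), and of 14 ABA-associated genes 2 rose (median 0.56, camera adjusted p = 0.0171; adjusted p = 0.341 with an estimated correlation). Both list calls were lost without control replicate 2 (adjusted p = 0.0651 and 0.0869) and without ABA+JA replicate 2 (adjusted p = 0.078 and 0.341). Mitosis genes fell in 15 of 16 cases (median -2.93, camera adjusted p = 3.1e-16; adjusted p = 0.117 with an estimated correlation) and ribosomal protein genes in 70 of 118 (median -0.83, camera adjusted p = 1.3e-36; adjusted p = 0.117 with an estimated correlation). Replicates 1 and 2 lay at 0.13 and 0.307 on the time axis, along which both lists differ. In all, 753 probe sets were higher and 1352 lower, and the total of 2105 was 835 and 904 without control replicates 1 and 2, 1366 without replicate 2 of ABA+JA, and 263 when fitted to the groups compared alone.

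Against JA alone at 24 h, ABA+JA gave 0 calls in limma, with 745 probe sets at an unadjusted p under 0.05. That is less than the 0.05 share of 22746 probe sets for unchanged groups, so the test may have been too strict here. There were 67 calls without JA replicate 1, 144 without ABA+JA replicate 1 and 137 without both. The ABA response genes were higher as a list (median 1.09, camera adjusted p = 0.000551; adjusted p = 0.331 with an estimated correlation), with no gene called, also when adjusted over the list alone. The call of the list was lost without JA replicate 2 (adjusted p = 0.346). Ribosomal protein and mitosis genes were lower as lists, also with no gene called (medians -0.16 and -0.85, camera adjusted p = 5.71e-05 and 8.38e-06; adjusted p = 0.801 and 0.616 with an estimated correlation). Without JA replicate 2 both lists stood in the other direction (adjusted p = 0.0459 and 0.951), and without ABA+JA replicate 1 the ribosomal call was lost (adjusted p = 0.0785). Against ABA alone (0.402 to 0.481 on the time axis, ABA+JA at 0.13 and 0.307), late embryogenesis abundant genes fell in 13 of 23 cases (median -2.54, camera adjusted p = 3.82e-14; adjusted p = 0.0378 with an estimated correlation). Here 1224 probe sets were higher and 952 lower, and the total of 2176 was 1422 without ABA replicate 1, 657 without ABA+JA replicate 1, 766 without replicate 1 of both JA and ABA+JA, and 328 when fitted to the groups compared alone.

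In the interaction of ABA and JA at 24 h, some genes that ABA raised lay below the sum. Here too the subtracted arrays of ABA alone lay at 0.402 to 0.481 on the time axis, against 0.893 and 0.971 for the controls. LEA4-5 read -5.50 ± 0.54 (adjusted p = 3.76e-05), AT2G16630 -7.17 ± 0.56 (adjusted p = 3.05e-06), AT3G15670, of the late embryogenesis abundant family, -5.52 ± 0.73 (adjusted p = 0.000474) and AT5G07330 -6.30 ± 0.81. AT3G02480 read -7.30 ± 1.27 and OSM34 -5.84 ± 1.06, and both calls were lost when fitted to the groups compared alone (adjusted p = 0.146 and 0.114). Added to its control level, both OSM34 changes reach above 13.91, the highest value on any array. OSM34 could therefore only lie below the sum. AT5G26270 lay above the sum by 3.61 ± 0.41 (adjusted p = 0.000102). Of 23 late embryogenesis abundant genes 9 lay below the sum (median -2.72, camera adjusted p = 1.14e-10) and of the 5 ABA response genes 2, or 4 when adjusted over the list alone (median -3.76, camera adjusted p = 1.07e-05), each with adjusted p = 0.0498 with an estimated correlation. Over 15 late embryogenesis abundant genes raised by ABA at 24 h, the mean level was 3.73 and 4.42 on replicates 1 and 2 of ABA+JA, 3.17 to 3.58 on arrays without ABA and 6.83 to 8.54 with ABA alone. In all, 258 probe sets lay above the sum and 273 below it, or 143 and 251 after quantile scaling. The total of 531 was 242 and 290 without control replicates 1 and 2, 324 without ABA replicate 1, 263 without ABA+JA replicate 1, 151 without replicate 1 of both JA and ABA+JA, and 92 when fitted to the groups compared alone. Without both replicate 1 arrays, OSM34 lost its call (adjusted p = 0.0937).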

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

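The change of the ABA response with time was 1 of the 23 comparisons in the design. The other tests of this part were chosen after the results had been seen. Differences between the times are given here for 5 results, which no test picked out. Other lists also changed with time for ABA, such as nuclear photosynthesis genes (above). The response to ABA differed between 3 h and 24 h in 2170 probe sets, that to SA in 15 and that to JA in 93. ABA alone had 3 arrays at each time and SA and JA 2, and the JA arrays at 24 h lay at 0.105 and 0.624. These counts therefore do not rank the hormones. For ABA, mitosis genes had a median difference of -4.27 log2 units and genes of cytosolic ribosomal proteins one of -0.922. These lists also differed between the controls, where ribosomal protein genes had a median of 0.98 and mitosis genes one of 2.01 at 24 h against 3 h.

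The arrays of ABA alone lay at one place between the 3 h and 24 h arrays at both times. Their mean position at 24 h minus that at 3 h was -0.0423, against 0.818 for the controls, so these arrays may come from separate cultures in another state, which cannot be told apart from an effect of ABA on the same cultures. A constant offset of these arrays, as from an array batch, did not match as the whole cause, since their shift from the control was 0.337 to 0.435 at 3 h and -0.53 to -0.451 at 24 h, a mean change of -0.861. ABA as the sole cause, whatever else was added, did not match either, since the highest position of the combined arrays at 3 h was -0.157, against 0.451 for the lowest array of ABA alone.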

How the results depend on the processing

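Of 2166 list calls recomputed under alternatives 2012 were the same, 151 weaker and 3 reversed, and of 2303 calls of named genes 2036, 266 and 1. These list calls used the preset correlation of 0.01, and the estimated correlation was not among the alternatives. Most list calls given in the Results were lost with an estimated correlation, and some were kept. The tally therefore does not show that the list calls hold when genes of a list are correlated. A trended robust prior, omission of the dimmest probe sets and quantile scaling kept all 23 total counts within 1.5 times. So did a replicate block, alone or within each time. Counts of 1 direction moved more in places. After quantile scaling, ABA+SA against ABA at 24 h gave 679 higher and 467 lower, against 1035 and 550 before. Under the block 3 of 155 list calls and 5 of 177 calls of named genes ended, and under the block within each time 5 and 2. Deviations of arrays with the same number correlated over 0.1 in 32 of 66 pairs of groups (-0.338 to 0.699), in all 10 pairs of 3 h groups other than ABA alone (0.253 to 0.553), in 0 of 5 with ABA alone at 3 h (-0.243 to -0.021) and in 11 of 15 at 24 h (-0.0598 to 0.699). This is a hint of pairing within a time from the data, not the design; the labels do not say what a number marks, and the block was not used elsewhere. The cause was not tested unless arrays were fewer.

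Array weights gave ABA at 3 h replicates 2 and 3, which are nearly equal, 7.01 and 3.76 against 0.175 for replicate 1, so that weighted counts treat them as precise replication. With these 2 averaged instead, all 6 counts stayed within 1.5 times. With array weights the counts were 7882 for ABA at 3 h, 159 for JA at 3 h, 6950 for ABA, 135 for SA and 591 for JA at 24 h, 2521 and 3797 for the SA and JA interactions at 3 h. For ABA+SA at 24 h they were 1604 against control, 1227 against SA, 3712 against ABA and 744 for the interaction, and 5700 for the ABA change with time. Overlaps with ABA were 10 (SA, 3 h), 74 (JA, 3 h) and 43 (SA, 24 h). Fitted to the groups compared alone, counts were 37 (JA, 3 h), 28 (SA, 24 h), 0 (JA, 24 h), 3589 (ABA+SA against ABA, 3 h), 452 (the same, 24 h), 86 (SA interaction, 24 h), 263 (ABA+JA against control, 24 h), 328 (against ABA) and 92 (JA interaction, 24 h), and overlaps 3 (SA, 3 h), 9 (SA, 24 h) and 91 (JA, 24 h). By title, the SA interaction at 3 h was 884 and the correlation of hormone differences reversed to 0.357. Also reversed were JRG21 in the SA interaction at 3 h by title (-0.617), the JA-associated list of ABA+SA against SA at 3 h by title (adjusted p = 0.885), and, without JA 24 h replicate 2, the ribosomal (0.0459) and mitosis (0.951) lists of ABA+JA against JA at 24 h (5.71e-05 and 8.38e-06 with all arrays), whose adjusted p without 1 array ranged from 2.16e-14 to 0.0785 and from 8.17e-10 to 0.951. Without replicate 1 of both JA and ABA+JA at 24 h, counts were 390 (JA), 137 (ABA+JA against JA), 766 (against ABA) and 151 (interaction), and the overlap 188. With both changes at least 2-fold, overlaps were 3 (SA, 3 h) and 10 (SA, 24 h).

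Leaving out 1 array at a time gave, at 3 h, 1966 to 3850 for ABA, 22 to 25 for SA and 41 to 53 for JA, and at 24 h 2041 to 3527, 63 to 98 and 271 to 2209. ABA+SA at 3 h gave 3204 to 4441 against control, 2565 to 3757 against SA, 3619 to 5349 against ABA and 751 to 1540 for the interaction. ABA+JA at 3 h gave 2129 to 2378, 1972 to 2606 (against JA), 2482 to 4161 and 738 to 1619. At 24 h ABA+SA gave 495 to 550, 170 to 285, 395 to 1155 and 76 to 186, and ABA+JA 835 to 1447, 0 to 144, 657 to 2394 and 242 to 710. The ABA change with time gave 1152 to 2331. Overlaps gave 3 to 7 (SA, 3 h), 9 to 29 (JA, 3 h), 6 to 39 (SA, 24 h) and 122 to 1060 (JA, 24 h), and the correlation of hormone differences -0.405 to -0.227 at 3 h and 0.55 to 0.718 at 24 h. List calls numbered 148 to 167 and named genes 151 to 176.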

Other observations

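At 24 h, 860 probe sets were higher and 445 lower with SA than with JA. The total of 1305 was 564 and 367 without replicates 1 and 2 of SA, 394 and 2236 without replicates 1 and 2 of JA, and 38 when fitted to the groups compared alone. On the time axis, along which ribosomal protein genes differed in the controls (median 0.98), JA lay at 0.105 and 0.624 and SA at 0.963 and 1.04. Ribosomal protein genes were higher in 47 of 118 cases (median 0.77, camera adjusted p = 3e-35; adjusted p = 0.129 with an estimated correlation). Between the combinations at 24 h, 739 were higher and 342 lower with ABA+SA than with ABA+JA. That total of 1081 was 665 and 249 without replicates 1 and 2 of ABA+SA, 340 and 1611 without replicates 1 and 2 of ABA+JA, and 40 when fitted to the groups compared alone. On the same axis ABA+JA lay at 0.13 and 0.307, ABA+SA at 0.665 and 0.753 and the 3 h controls at 0.0996 and 0.128. Ribosomal protein genes were higher in 49 of 118 cases (median 0.78, camera adjusted p = 3.01e-39; adjusted p = 0.069 with an estimated correlation), and late embryogenesis abundant genes in 4 of 23 (median 0.50, camera adjusted p = 0.00553; adjusted p = 0.384 with an estimated correlation).

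OSM34 read 10.53 ± 0.76 (SD, n = 2) in the control at 3 h and 4.05 ± 0.34 (n = 2) at 24 h. GAT1_2.1 spread widely between replicates with JA at 24 h, at 8.65 ± 4.34 (n = 2). Replicate 1 of JA and replicate 1 of ABA+JA at 24 h correlated at r = 0.9934 across probe sets, which are not independent replicates, and the SD of their difference was 0.259 log2 units, against 0.735 and 0.690 within their own groups.

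Of the tests below, the correlation of hormone differences was written before the data were examined and the others were chosen after the results had been seen. For the 3 h arrays with contradictory labels, treatment names swapped between the combined groups fit the correlation of -0.357 of (ABA+SA minus ABA+JA) with (SA minus JA). A biological account, in which ABA given with SA raises JA genes, gave a median of 1.78 over 76 probe sets higher with JA alone at 3 h in the arrays labelled ABA+SA against ABA alone, and 0.16 in those labelled ABA+JA. For the JA genes this account cannot be told apart from a swap, which gives the same values. Source names that are right, with SA genes that follow SA, did not match: over the 31 probe sets higher with SA alone at 3 h, arrays labelled ABA+SA minus those labelled ABA+JA had a median of -1.51, and -1.8 to -1.28 over the 4 pairs of single arrays. Against ABA alone, the same 31 probe sets had a median of 0.126 in the arrays labelled ABA+SA and 1.97 in those labelled ABA+JA. Of the 31, 30 were lower in the arrays labelled ABA+SA than in those labelled ABA+JA. For these probe sets the values argue against the source names, unless combined treatment at 3 h alone reverses the genes of both hormones. Such a reversal was not tested. The titles may therefore name the treatments.

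Replicate 1 of JA and of ABA+JA at 24 h lay near the 3 h controls on the time axis. RNA of a 3 h JA treatment did not match over 67 probe sets, where the lower of their positions between JA at 3 h (0) and replicate 2 at 24 h (1) was 0.63. These probe sets were called on the same JA arrays at 3 h, which may move other arrays away from 0. Over all probe sets, the SD of the difference from JA at 3 h was 0.423 (JA) and 0.402 (ABA+JA) for its replicate 1, and 0.567 and 0.562 for its replicate 2. Between those JA arrays at 3 h it was 0.544. From replicate 1 of the 3 h control, without JA, the SD was 0.43 and 0.406, so it gives no measure of JA treatment time. On replicate 1 of JA and of ABA+JA at 24 h, AT2G38240 read 7.959 and 7.471, against 11.19 and 11.05 with JA at 3 h. PYK10 read 9.475 and 9.848 against 7.814 and 7.803, while JRG21, at 11.71 and 11.61, lay between its 3 h values of 11.16 and 11.98. A 3 h treatment did not match AT2G38240 and PYK10, genes picked after their values were seen, and is not excluded. Over 15 late embryogenesis abundant genes, replicate 1 of ABA+JA stood 0.367 log2 units above the 6 arrays at 24 h without ABA, which cannot be told apart from cells that had no ABA. Replicate 2 of ABA+JA minus the lowest array of ABA alone was -2.41 (4.42 against 6.83), but ABA+SA, at 5.34 and 5.56, also lay below that array. A lower ABA response with JA therefore cannot be told apart from arrays of ABA alone that stand apart.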
